A study of Mus musculus with 16 samples.

How the data were processed

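RNA from frozen livers of 16 mice was measured by bulk RNA sequencing. The labels give 4 groups of 4 mice, wild type (Mfap2+/+) and knockout (Mfap2-/-) after 8 weeks of carbon tetrachloride (CCl4), and the same genotypes after 8 weeks of CCl4 and 4 weeks of cessation, here called reversal. The labels number separate mice, and each library was treated as one animal. The mouse numbers did not pair the libraries of the 2 genotypes, so the fits have no pairing term.

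The values were taken as FPKM, fragments scaled by transcript length and by the total of the library, as deposited by the authors in one table per stage. Per the submitters' processing notes, HISAT, Cufflinks and the mouse build mm10 were used. Their versions, the annotation, the strand setting and the gene filter are not given in the sources used here. The table headers name no unit, and for the reversal table TPM over a filtered gene set is not excluded. Per the labels' protocols, the 8-week libraries were made with a NEBNext Ultra kit, while for the reversal libraries that kit or a VAHTS Universal kit is named. Stage, table and library kit therefore cannot be told apart, and no level was tested between stages. The 8-week table lists no mitochondrial gene and the reversal table no Y-linked gene, so a share of such transcripts was computed in only one of the tables. Gene symbols and identifiers are those of the tables, and positions come from the GENCODE annotation of mm10, in which 13713 of 13715 and 12917 of 12922 listed identifiers were found.

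The tables hold no counts. Whole reads would make the ratios of low genes between libraries recur across genes. In the 8-week table, among genes with a mean of at most 0.3 FPKM, such recurrence exceeded that of randomly shifted ratios in 0 of 28 library pairs, and the reversal values, rounded to 2 decimals, are too coarse for this check. Read depth is therefore unknown, and no counting interval or detection floor is given. The FPKM of a library sum to between 428142 and 478062 at 8 weeks and between 878889 and 959698 after reversal. FPKM are shares of a total, so a change in a few abundant transcripts shifts every other gene of a library. A value of 0 in such a table can be a failed estimate, and Mfap2 is therefore given per library.

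Genes with a mean of at least 0.5 FPKM over the 8 libraries of a table were tested, on log2(FPKM + 1), with the values scaled as deposited. Differences are knockout minus wild type on that scale, which understates the change of genes with low values. Each genotype comparison was fitted within its own table with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trended and robust prior variance, statmod 1.5.0), 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The difference between the stages' genotype effects was an interaction term in one limma fit over all 16 libraries, for genes tested in both tables. Single values (Mfap2, library measures and per-mouse scores) were compared with 2-sided exact permutation tests over all 70 assignments of 8 libraries, for which the smallest possible p is 0.0286. The core fibrosis score of a mouse is the mean, over the genes of that list, of log2(FPKM + 1) minus the gene's mean over the 8 libraries of the table.

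Before the data were examined, 50 gene lists were fixed, 27 of pathways, 12 of cell types and 11 of sample quality or other tissues. Mfap2 was left out of every list. Lists with at least 5 tested members were compared with all other genes by camera (limma) with an inter-gene correlation preset at 0.01, which was possible for 45 lists at 8 weeks and 46 after reversal. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were run beside it. Members were also counted at an adjusted p under 0.05 when adjusted over the list alone.

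The genes named were chosen by a rule fixed at the same time. It takes Mfap2; up to 10 genes per direction past the threshold without overlap between the genotypes, or the 5 with the smallest p in a direction where none passes; up to 4 members with the smallest p that move with each list past its test; and a fixed panel of fibrosis and liver genes. Other genes are named as chosen after their values were seen. Of the genes that the rule takes, the text gives the values of some, picked after the values were seen. One further gene that it takes was left out of the gene results and is not reported here.

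The steps were tested on simulated data, with 200 changed genes in each table, drawn on the means and spreads of the real tables. The simulated noise was independent between genes, without the structure of the libraries or the shift of the median gene described below. The counts that follow therefore check the steps and are not error rates for the real tables. At 8 weeks, 50 of 100 genes changed by 1 log2 unit and 89 of 100 changed by 2 were recovered, with 4 false calls among 143. After reversal these were 56 and 94 of 100, with 10 false calls among 160. For the stage difference, over genes whose simulated changes differed between the tables by 1 or 2, 66 of 182 and 155 of 178 were recovered, with 12 false calls among 234.

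Alternatives planned for each result were a pseudocount of 0.1, no filter or a mean of at least 2 FPKM, median-ratio scaling, quantile normalization, plain empirical Bayes, library weights, the mouse number as a block, one fit over all 16 libraries, a 2-fold requirement and leaving out each library in turn. Added after the data were seen were fits without the libraries that stood apart, the average of the genotype effects of the 2 stages, regroupings with each library left out for the correlation between the stages, and the mean differences of the gene lists without each library and without those that stood apart. The result counts were also computed for all 35 splits of 8 libraries into 4 and 4, or for 100 regroupings drawn within the tables. Figures were drawn with matplotlib 3.10.9.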

Results

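Liver gene expression was measured in 16 mice that had received intraperitoneal carbon tetrachloride (CCl4), a hepatotoxin that injures hepatocytes around the central vein and leads to fibrosis when given repeatedly. At each stage 4 wild-type mice and 4 mice lacking Mfap2 were sampled, either after 8 weeks of CCl4 or after 8 weeks of CCl4 followed by 4 weeks without it, a period in which fibrosis can regress. Mfap2 encodes microfibril-associated glycoprotein 1 (MAGP1), an extracellular matrix protein bound to fibrillin microfibrils, and the study asked what it does in experimental liver fibrosis. Mice without CCl4 were not analysed here. At 8 weeks 13715 genes were listed and 11928 tested, and after reversal 12922 were listed and 11032 tested. Read depth is unknown, and the FPKM of a library sum to 428142 to 478062 at 8 weeks and 878889 to 959698 after reversal.

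Mfap2 (ENSMUSG00000060572, chromosome 4, 141010418 to 141015984 of mm10, plus strand) was read in every wild-type library and listed at 0 in all 8 knockout libraries. At 8 weeks it stood at 0.902, 0.972, 1.40 and 3.07 FPKM in wild-type mice 1 to 4. After reversal the wild-type mice had 0.17, 0.21, 0.44 and 0.47 FPKM. The genotypes differed at each stage (exact permutation p = 0.0286, the smallest 4 mice against 4 can give). No fold is given against a group at 0.

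The makeup of the libraries also differed. Albumin (Alb), an abundant hepatocyte transcript, stood at 36951 ± 8366 FPKM (SD, n = 4) in wild-type and 24089 ± 5066 FPKM in knockout livers at 8 weeks (exact permutation p = 0.0286). After reversal it stood at 37939 ± 7200 and 34330 ± 13462 FPKM (exact p = 0.714). The first principal component held 53.5% of the variance at 8 weeks, where wild-type mice 1 and 2 lay at -45.7 and -49.4 and the other 6 libraries between -10.4 and 38.0. After reversal it held 45.9%, with wild-type mouse 1 at -35.3, knockout mouse 3 at -36.3 and knockout mouse 2 at -17.3, and the other 5 libraries between 15.2 and 20.03. These 3 libraries had 38.1%, 37.5% and 32.4% of their FPKM in mitochondrial transcripts, against 23.5% to 29.8% in the others. The median gene was 0.23 higher in the knockout at 8 weeks and 0.10 higher after reversal on the log2 scale. Of all genes tested, 82.6% were higher in the knockout at 8 weeks and 70.7% after reversal. The counts of list genes higher or lower below are to be read beside these shares. Only list values described against the median gene have that median subtracted. Mean log2 differences and scores of lists are given without that correction. Among genes with an unadjusted limma p under 0.05, 88.8% were higher in the knockout at 8 weeks as deposited, 55.3% after median-ratio scaling and 56.6% after quantile normalization. After reversal the shares were 82.2%, 54.7% and 51.2%.

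The first comparison asked how livers with and without Mfap2 differed after 8 weeks of CCl4, when fibrosis is established. Genes of the fibrous matrix were higher in the knockout. Col1a1 and Col3a1, which encode chains of fibrillar collagens, stood at 13.6 ± 1.61 and 23.6 ± 4.47 FPKM (SD, n = 4) in wild-type livers and at 28.8 ± 12.4 and 48.2 ± 14.2 FPKM in knockout livers, with no overlap between the genotypes. Timp1, an inhibitor of matrix metalloproteinases, stood at 7.27 ± 1.87 and 21.9 ± 9.52 FPKM, and Sparc, a collagen-binding matricellular protein, at 65.7 ± 15.1 and 145 ± 47.7 FPKM. The core fibrosis score, which averages 27 such genes, was -0.41 ± 0.20 in wild-type and 0.41 ± 0.47 in knockout mice, a difference of 0.82 without overlap (exact permutation p = 0.0286). Of all genes tested, 82.6% were higher in the knockout. All 27 genes of the list were (26 and 27 after the scalings, which are always given in the order median-ratio, quantile). Of these, 16 were past the threshold when adjusted over the list alone and 0 when adjusted over all genes tested. The list lay 0.63 above the median gene (camera adjusted p = 1.4e-09, and adjusted p = 0.41 with an estimated correlation). Without wild-type mice 1 and 2 the score difference was 0.68 (exact p = 0.133, where 2 against 4 allows no less than 0.0667). It missed 0.05 when any one wild-type mouse or knockout mouse 3 was left out (exact p = 0.0571 to 0.0857). Leaving out a mouse cannot make the genotypes overlap, and 3 against 4 allows no p below 0.0286.

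**Figure D1:**
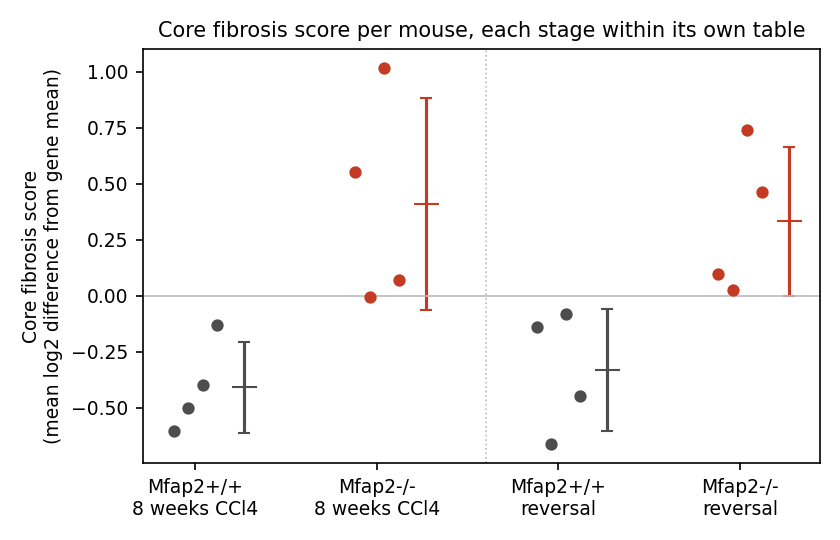
Core fibrosis score of each mouse (dots, 4 per group) with group mean and SD (bars); the vertical axis is the mean log2(FPKM + 1) difference from the gene means of the same table, over 27 genes at 8 weeks and 26 after reversal. Wild-type mice lie between -0.60 and -0.13 at 8 weeks and between -0.66 and -0.08 after reversal, knockout mice between -0.00 and 1.02 and between 0.03 and 0.74.

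Mmp13, an interstitial collagenase, was the one gene to pass over all 11928 genes at 8 weeks. Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331 of mm10, plus strand) rose from 2.94 ± 0.897 to 17.2 ± 3.55 FPKM (SD, n = 4), a log2 difference of 2.22 ± 0.23 (SE, limma adjusted p = 8.1e-04), with every knockout mouse above every wild-type mouse. Its adjusted p was 0.053 after median-ratio scaling and 0.058 after quantile normalization, and ranged from 2.2e-06 to 0.143 over 18 alternatives. Mmp12, the macrophage elastase, stood at 27.4 ± 10.7 and 78.1 ± 24.4 FPKM, and Plau, the urokinase plasminogen activator, at 3.34 ± 1.52 and 10.2 ± 1.46 FPKM. In the list of matrix degradation and its inhibitors 30 of 31 genes were higher (28 and 26 after the scalings), 8 past the threshold when adjusted over the list alone and 1 over all genes tested. It rose as a list (camera adjusted p = 3.3e-06, and adjusted p = 0.45 with an estimated correlation). Its mean log2 difference was 0.72, and 0.40 without wild-type mice 1 and 2.

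Markers of activated stellate cells and myofibroblasts, the collagen-producing cells of the injured liver, were higher for 18 of 20 genes (16 and 17 after the scalings). Tagln stood at 19.5 ± 10.4 FPKM (SD, n = 4) in wild-type and 59.9 ± 25.02 FPKM in knockout livers, and Acta2, alpha smooth muscle actin, at 10.4 ± 7.06 and 28.1 ± 14.3 FPKM, with overlap (limma adjusted p = 0.25). Of these, 5 passed when adjusted over the list alone and 0 over all genes tested (camera adjusted p = 1.2e-04, and adjusted p = 0.42 with an estimated correlation). In the TGF-beta list, which holds the ligands, receptors and targets of the main profibrotic cytokine, all 28 genes were higher (27 and 26 after the scalings), with Tgfb1 at 11.9 ± 2.56 and 23.3 ± 6.29 FPKM. There 6 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.3e-06, and adjusted p = 0.51 with an estimated correlation). Per-mouse scores of the TGF-beta list, formed like the core fibrosis score, overlapped between the genotypes (exact permutation p = 0.0857). Wild-type mouse 4 was at 0.19, above knockout mice 2 and 4 at 0.002 and 0.04. Fibrillar collagens (14 of 14 genes higher, 13 and 11 after the scalings) and proteoglycans and matricellular proteins (22 of 24, 20 and 19 after the scalings) also rose as lists (camera adjusted p = 2.5e-04 and 0.0088, and adjusted p = 0.47 and 0.64 with an estimated correlation). Of their genes 7 and 6 passed when adjusted over the list alone, and 0 over all genes tested. Without wild-type mice 1 and 2 the mean log2 difference fell from 0.66 to 0.38 for the TGF-beta list and from 0.47 to 0.30 for proteoglycans.

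Other matrix lists passed with less room. In the list of collagen processing, 21 of 24 genes were higher (19 and 18 after the scalings), among them the collagen chaperone Serpinh1 at 21.2 ± 7.82 and 52.8 ± 14.6 FPKM (SD, n = 4). For basement membrane genes the count was 17 of 18 (15 and 13 after the scalings), for microfibril and elastic fibre genes 19 of 19 (14 after each) and for integrin and focal adhesion genes 27 of 27 (22 and 21). As deposited, 82.6% of all genes tested were higher. Fbn1, which encodes the fibrillin that MAGP1 binds, stood at 0.993 ± 0.417 and 2.36 ± 1.26 FPKM (limma adjusted p = 0.22), and Emilin1, an elastic fibre glycoprotein, at 11.1 ± 2.43 and 21.3 ± 4.39 FPKM. The camera adjusted p of these 4 lists were 0.0057, 0.013, 0.014 and 0.0062, and with an estimated correlation the adjusted p were 0.62, 0.57, 0.65 and 0.65. In the same order 6, 5, 2 and 2 genes passed when adjusted over the list alone, and 0 over all genes tested. The calls were lost without knockout mouse 1 (collagen processing), without wild-type mouse 4 (basement membrane), with a mean of at least 2 FPKM or without wild-type mouse 3 or knockout mouse 3 (microfibrils), and without wild-type mice 1 and 2 together (integrins). Without those mice the mean log2 difference fell from 0.46 to 0.25 for collagen processing, 0.44 to 0.29 for basement membrane, 0.46 to 0.25 for microfibrils (0.28 without knockout mouse 3) and 0.48 to 0.11 for integrins.

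Inflammatory genes were also higher in the knockout at 8 weeks. All 31 interferon response genes were higher (31 and 30 after the scalings), among them Isg15, a ubiquitin-like protein induced by interferon, at 26.2 ± 7.56 FPKM (SD, n = 4) in wild-type and 88.9 ± 41.8 FPKM in knockout livers, and Oas1a at 13.4 ± 2.70 and 31.4 ± 7.88 FPKM. Markers of monocytes and recruited macrophages were higher for 24 of 24 genes (23 and 24). S100a4 stood at 6.16 ± 1.90 and 17.5 ± 3.85 FPKM, and Ly6c2, a marker of inflammatory monocytes, at 7.40 ± 2.76 and 29.5 ± 18.5 FPKM. Among chemokines and cytokines 27 of 28 were higher (23 and 24), with the monocyte attractant Ccl7 at 4.87 ± 1.93 and 25.3 ± 14.2 FPKM and Il1rn, the interleukin-1 receptor antagonist, at 19.3 ± 10.1 and 44.9 ± 10.98 FPKM. Adjusted over the list alone, 26, 12 and 17 genes of these lists passed, and 0 over all genes tested. The camera adjusted p were 4.5e-12, 1.4e-09 and 3.3e-06, and with an estimated correlation the adjusted p were 0.41, 0.36 and 0.42. Genes of MHC class II antigen presentation were higher for 8 of 8, also after each scaling (camera adjusted p = 0.0063, and adjusted p = 0.48 with an estimated correlation), with 0 past the threshold when adjusted over the list alone or over all genes, and this call was lost without wild-type mouse 4. The interferon difference lay mainly in knockout mice 3 and 4, with list scores (mean log2 difference from the gene means) of 1.00 and 0.85. Knockout mice 1 and 2 were at 0.08 and -0.19 and the wild-type mice between -0.61 and -0.34. For monocytes and macrophages the mean log2 difference fell from 0.91 to 0.59 without wild-type mice 1 and 2. Their list scores overlapped (exact permutation p = 0.0857), with wild-type mouse 4 at 0.22 above knockout mice 2 and 4 at 0.21 and 0.17.

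Genes of hepatocyte metabolism were lower in the knockout at 8 weeks, beside the lower albumin. Cytochrome P450 and phase II enzymes, which process drugs and toxins, were lower for 50 of 55 genes (54 and 51 after the scalings) and pericentral hepatocyte genes, from the zone that CCl4 injures, for 13 of 22 (16 and 17). Cyp2e1, the enzyme that activates CCl4, stood at 197 ± 21.6 FPKM (SD, n = 4) in wild-type and 106 ± 44.3 FPKM in knockout livers, Por, the reductase that supplies P450 enzymes with electrons, at 290 ± 62.7 and 149 ± 33.8 FPKM, and Cyp27a1, of bile acid synthesis, at 98.2 ± 10.6 and 55.1 ± 4.92 FPKM, each without overlap. These lists lay at -0.79 and -0.69 relative to the median gene (camera adjusted p = 2.7e-40 and 8.4e-11), and they were the 2 lists that also passed with an estimated correlation (adjusted p = 0.033 and 0.021). In them 5 and 6 genes fell when adjusted over the list alone, and 0 over all genes tested. The 2 lists share genes, Cyp2e1 among them. Per-mouse scores of the pericentral list overlapped between the genotypes (exact permutation p = 0.0571), and those of the P450 list did not (exact permutation p = 0.0286). The mean log2 difference of the P450 list was -0.58, and -0.37 without wild-type mice 1 and 2.

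All 27 genes of bile acid synthesis and transport and all 29 of the urea cycle and amino acid catabolism were lower, also after the scalings except for 1 urea cycle gene after quantile normalization. Akr1d1, a reductase of bile acid synthesis, stood at 13.9 ± 6.22 FPKM (SD, n = 4) in wild-type and 3.57 ± 0.344 FPKM in knockout livers, the transporter Slco1a4 at 18.3 ± 7.53 and 5.45 ± 0.198 FPKM, and Bhmt, which remethylates homocysteine, at 367 ± 222 and 49.3 ± 14.2 FPKM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 4.96 ± 4.04 and 0.355 ± 0.269 FPKM. Both lists fell (camera adjusted p = 7.0e-33 and 1.4e-36, and adjusted p = 0.051 and 0.14 with an estimated correlation), with 10 genes each past the threshold when adjusted over the list alone and 0 over all genes tested. The per-mouse scores of both lists overlapped between the genotypes (exact permutation p = 0.0571 and 0.0857). Hepatocyte identity genes were lower for 23 of 25 (25 and 23 after the scalings), periportal genes for 20 of 23 (22 and 19), fatty acid oxidation genes for 29 of 37 (35 and 33) and NRF2 targets for 18 of 31 (28 and 21). These lists fell as well (camera adjusted p = 6.5e-18, 3.3e-17, 8.4e-11 and 2.6e-08, and adjusted p = 0.18, 0.18, 0.40 and 0.051 with an estimated correlation), with 0 of their genes past the threshold when adjusted over the list alone or over all genes. The calls for periportal and fatty acid oxidation genes were lost without wild-type mice 1 and 2, which had 46316 and 41550 FPKM of albumin. Without these mice the mean log2 difference of urea cycle genes fell from -0.78 to -0.31, of bile acid genes from -0.68 to -0.44, of hepatocyte identity genes from -0.40 to -0.20 and of periportal genes from -0.57 to -0.06, while that of NRF2 targets went from -0.13 to -0.26 (-0.07 without wild-type mouse 4). The fatty acid oxidation difference of -0.15 was -0.01 without them, and with one mouse left out it lay between -0.30 (without wild-type mouse 4) and -0.01 (without wild-type mouse 1), with -0.08 and -0.05 without wild-type mouse 3 and knockout mouse 1.

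Sinusoidal endothelial genes were higher for 22 of 23 (21 after each scaling) and vascular endothelial genes for 15 of 16 (11 and 9 after the scalings). Both lists rose (camera adjusted p = 6.7e-04 and 0.046, and adjusted p = 0.57 and 0.65 with an estimated correlation). The first call was lost without wild-type mouse 3. The second was lost after either scaling, with the mouse number as a block and without wild-type mouse 3 or 4 or knockout mouse 1 or 3. Kupffer cell, neutrophil, T and NK cell, B and plasma cell and cholangiocyte markers did not pass (camera adjusted p = 0.43, 0.84, 0.27, 0.81 and 0.083). Cholangiocyte markers did pass upward after either scaling, with a mean of at least 2 FPKM and with the mouse number as a block. They also passed without wild-type mouse 3 or 4 or knockout mouse 2. Kupffer cell, neutrophil and T and NK cell markers passed only in some fits that left mice out. Red blood cell transcripts were higher for 9 of 9, also after each scaling (camera adjusted p = 0.0021, and adjusted p = 0.54 with an estimated correlation), with the globin Hbb-bs at 1187 ± 1112 FPKM (SD, n = 4) in wild-type and 2651 ± 1090 FPKM in knockout livers (exact permutation p = 0.114). Circadian clock, male-biased and female-biased liver genes fell as lists (camera adjusted p = 1.7e-04, 2.3e-07 and 0.0029, and adjusted p = 0.18, 0.42 and 0.18 with an estimated correlation). Their mean log2 differences were -0.09, -0.22 and -0.19. With one mouse left out they ranged from -0.18 (knockout mouse 3) to -0.01 (knockout mouse 1), from -0.76 (wild-type mouse 4) to 0.17 (knockout mouse 1; 0.09 without wild-type mouse 3) and from -0.37 (wild-type mouse 3) to -0.01 (wild-type mouse 4). Both sex-biased calls were lost without wild-type mice 1 and 2, the female-biased one also after either scaling and with a mean of at least 2 FPKM. Complement and acute phase, glycolysis and cell cycle genes passed downward relative to other genes (camera adjusted p = 0.013, 0.033 and 0.028, and adjusted p = 0.57, 0.42 and 0.64 with an estimated correlation). Their own mean log2 differences were 0.16, 0.09 and 0.07, above 0, and their medians -0.08, 0.16 and 0.04. The means ranged from 0.08 to 0.25, 0.03 to 0.14 and -0.01 to 0.17 with one mouse left out, lowest without wild-type mouse 4, knockout mouse 2 and knockout mouse 3. After median-ratio scaling the medians were -0.39, -0.14 and -0.15 and after quantile normalization 0.07, 0.16 and -0.24. All 3 calls were lost after median-ratio scaling and without wild-type mouse 1, wild-type mouse 2 or knockout mouse 4. Those of complement and glycolysis were also lost after quantile normalization and without knockout mouse 3, that of glycolysis without wild-type mouse 3 and that of cell cycle with a mean of at least 2 FPKM. Without wild-type mice 1 and 2 together the complement and cell cycle lists passed upward and the glycolysis list did not pass. The remaining 9 lists had camera adjusted p from 0.085 to 0.95. Red blood cell transcripts differed by a mean of 1.05, and by 0.57 without wild-type mice 1 and 2.

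Gene by gene, limma called 1 of 11928 genes at 8 weeks, 76 at an adjusted p under 0.1 (67 higher, 9 lower), and 1722 at an unadjusted p under 0.05 (1529 higher and 193 lower, where chance gives 596). The genotypes did not overlap for 750 genes higher and 73 lower, 6.90% of those tested, where chance gives 2.86%. This chance value, like the 596, holds only where no gene is shifted, and the median gene lay higher in the knockout. Besides Mfap2, the genes lower in the knockout with the smallest p were Eif4ebp3, a repressor of translation initiation, at 18.03 ± 12.9 FPKM (SD, n = 4) in wild-type and 1.90 ± 0.813 FPKM in knockout livers (limma adjusted p = 0.056), Akr1d1 (0.056), Slco1a4 (0.061) and Car14 (0.082), and none of them passed. The count was 1465 without wild-type mouse 4, 32 without knockout mouse 2, 4 without wild-type mouse 3 and 2 without wild-type mouse 1, mouse 2 or both. It was 1615 with library weights and 0 after median-ratio scaling, where limma gave 699 genes higher and 564 lower at an unadjusted p under 0.05. Fry called 0 of the 45 lists (smallest adjusted p = 0.097), where camera called 17 upward and 14 downward.

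**Figure D2:**
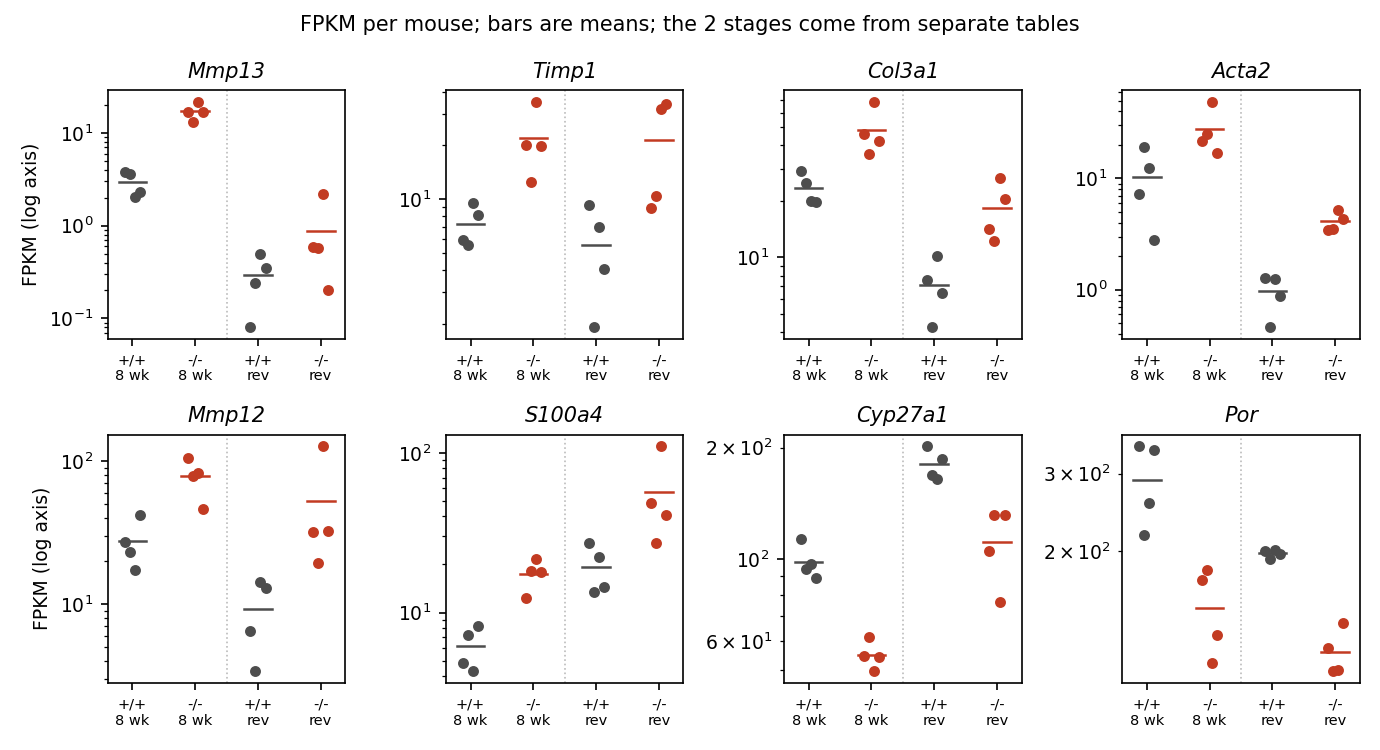
FPKM per mouse (dots, log axis) and group means (bars) of 8 genes in wild-type (+/+) and knockout (-/-) livers after 8 weeks of CCl4 (8 wk) and after reversal (rev), n = 4 per group; levels are comparable within a stage and not between stages, whose tables are separate. Mmp13 separates the genotypes at 8 weeks (means 2.94 and 17.2 FPKM) and Por at each stage (290 and 149, then 198 and 118 FPKM).

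The next comparison asked how the genotypes differed after 4 weeks without CCl4. Matrix and myofibroblast genes were again higher in the knockout. Acta2 stood at 0.965 ± 0.382 FPKM (SD, n = 4) in wild-type and 4.11 ± 0.824 FPKM in knockout livers, Col3a1 at 7.11 ± 2.46 and 18.4 ± 6.54 FPKM, and vimentin (Vim), an intermediate filament of mesenchymal cells, at 30.6 ± 3.64 and 67.1 ± 25.5 FPKM, each without overlap. Timp1 stood at 5.55 ± 3.24 and 21.4 ± 13.6 FPKM, with overlap. The core fibrosis score, over 26 genes, was -0.33 ± 0.27 in wild-type and 0.33 ± 0.33 in knockout mice, a difference of 0.67 without overlap (exact permutation p = 0.0286). Of all genes tested, 70.7% were higher in the knockout, and of the list all 26 (25 after either scaling). Of the 26, 9 were past the threshold when adjusted over the list alone and 0 when adjusted over all genes tested. The list lay 0.43 above the median gene (camera adjusted p = 5.0e-12, and adjusted p = 0.40 with an estimated correlation). The score difference missed 0.05 without wild-type mouse 2, wild-type mouse 4 or knockout mouse 3 (0.55, 0.63 and 0.53, exact p = 0.0571 each). Here too the genotypes did not overlap, and 3 against 4 allows no p below 0.0286. Without wild-type mouse 1 and knockout mouse 3 it was 0.59 (exact p = 0.1, the smallest 3 against 3 can give).

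The lists of stellate cells and myofibroblasts (18 of 18 genes higher, 16 and 15 after the scalings), fibrillar collagens (11 of 12, 10 after each) and TGF-beta (25 of 26, 23 and 20) rose after reversal. Tagln stood at 3.86 ± 1.23 FPKM (SD, n = 4) in wild-type and 9.12 ± 4.20 FPKM in knockout livers, and Tgfb1 at 3.10 ± 0.578 and 7.00 ± 1.84 FPKM, without overlap. Adjusted over the list alone, 5, 2 and 1 of their genes passed, and 0 over all genes tested (camera adjusted p = 8.4e-06, 1.3e-04 and 4.9e-04, and adjusted p = 0.41, 0.41 and 0.43 with an estimated correlation). Matrix degradation (26 of 28 genes higher, 24 and 23 after the scalings), proteoglycans (16 of 17, 13 after each) and microfibrils and elastic fibres (17 of 17, 17 and 16) rose as lists too (camera adjusted p = 7.0e-05, 1.2e-04 and 4.9e-04, and adjusted p = 0.47, 0.42 and 0.43 with an estimated correlation), with 0 genes past the threshold when adjusted over the list alone or over all genes. Mmp12 stood at 9.23 ± 5.15 and 52.7 ± 50.1 FPKM. Fbn1 stood at 0.185 ± 0.0794 and 0.522 ± 0.179 FPKM (exact permutation p = 0.0286), below the expression filter and so in none of the list tests. Basement membrane (14 of 15 genes, 11 and 10 after the scalings), collagen processing (17 of 20, 13 and 14) and integrin genes (24 of 26, 16 and 15) had camera adjusted p of 0.022, 0.047 and 0.024 (adjusted p = 0.42, 0.59 and 0.48 with an estimated correlation). The first 2 calls were lost with a mean of at least 2 FPKM and without wild-type mouse 4 or knockout mouse 2, collagen processing also without wild-type mouse 2 or 3 or knockout mouse 3, and the integrin call after either scaling and without wild-type mouse 4 or knockout mouse 3. Without knockout mouse 3 the mean log2 difference fell from 0.53 to 0.34 for matrix degradation and from 0.28 to 0.17 for collagen processing.

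Immune and acute phase genes were higher in the knockout after reversal. All 28 chemokines and cytokines were higher (26 after either scaling), with Ccl7 at 1.92 ± 0.226 FPKM (SD, n = 4) in wild-type and 5.93 ± 2.71 FPKM in knockout livers and the inflammatory cytokine Il1b at 2.75 ± 0.563 and 5.49 ± 0.886 FPKM. This was the one list that fry called (adjusted p = 0.030). Monocyte and macrophage markers were higher for 23 of 23, also after each scaling, among them lysozyme (Lyz2) at 208 ± 43.6 and 482 ± 154 FPKM. Complement and acute phase genes were higher for 31 of 33 (27 and 30 after the scalings), with serum amyloid Saa3 at 150 ± 51.9 and 358 ± 52.5 FPKM and Socs3, a feedback inhibitor of cytokine signalling, at 4.23 ± 0.389 and 10.5 ± 2.63 FPKM. Immediate early genes were higher for 16 of 16, also after each scaling, with the transcription factor Junb at 13.7 ± 2.98 and 29.4 ± 5.68 FPKM. Adjusted over the list alone, 13, 8, 7 and 2 genes of these lists passed, and 0 over all genes tested. Their camera adjusted p were 9.0e-11, 9.5e-11, 9.5e-07 and 1.2e-08, and with an estimated correlation the adjusted p were 0.27, 0.40, 0.40 and 0.40. MHC class II genes were higher for 9 of 9, also after each scaling (camera adjusted p = 0.0066, and adjusted p = 0.48 with an estimated correlation), a call lost without wild-type mouse 4 or knockout mouse 3. Interferon response genes did not pass (camera adjusted p = 0.48). Without knockout mouse 3 the mean log2 difference of MHC class II genes fell from 0.56 to 0.32.

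Genes of lipid and drug metabolism were lower in the knockout after reversal. Fatty acid oxidation genes, targets of PPAR-alpha, were lower for 33 of 37 (36 and 35 after the scalings), with the fatty acid hydroxylase Cyp4a10 at 561 ± 47.3 FPKM (SD, n = 4) in wild-type and 296 ± 42.2 FPKM in knockout livers. P450 and phase II enzymes were lower for 48 of 61 (51 and 49), with Por at 198 ± 4.16 and 118 ± 14.4 FPKM. Genes of fatty acid and triglyceride synthesis were lower for 18 of 29 (21 and 20), with the lipid droplet protein Plin5 at 17.8 ± 5.21 and 9.03 ± 2.32 FPKM. Adjusted over the list alone 1, 1 and 2 genes fell, and 0 over all genes tested (camera adjusted p = 9.9e-17, 3.1e-10 and 1.6e-05, and adjusted p = 0.40, 0.41 and 0.41 with an estimated correlation). Bile acid genes were lower for 17 of 28 (20 and 18), with Cyp27a1 at 180 ± 17.3 and 111 ± 26.3 FPKM and, in the other direction, Cyp7a1 at 10.7 ± 2.94 and 19.9 ± 10.1 FPKM (camera adjusted p = 7.6e-05, and adjusted p = 0.42 with an estimated correlation). Hepatocyte identity, periportal, urea cycle and pericentral genes were lower for 21 of 25 (22 and 21 after the scalings), 18 of 22 (20 and 18), 21 of 29 (22 and 21) and 18 of 26 (19 after each). Their camera adjusted p were 1.3e-05, 7.5e-06, 2.8e-05 and 0.010, and with an estimated correlation the adjusted p were 0.41, 0.41, 0.41 and 0.59. All 4 calls were lost without knockout mouse 3, which had 16731 FPKM of albumin, the lowest of the 8 libraries, and the pericentral call also after quantile normalization and without wild-type mouse 3 or 4 or knockout mouse 1. Without that mouse the mean log2 differences went from -0.14 to -0.003 for hepatocyte identity, -0.22 to -0.03 for periportal, -0.13 to 0.02 for urea cycle, -0.03 to 0.06 for pericentral, -0.13 to 0.02 for bile acid, -0.19 to -0.05 for P450 and -0.17 to -0.05 for fatty acid synthesis genes. Without wild-type mouse 3 the last 3 were -0.05, -0.05 and -0.11, and without wild-type mouse 1 they were -0.28, -0.40 and -0.28. The pericentral mean was also above 0 without wild-type mouse 3 or 4 (0.10 and 0.03).

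Clock genes were lower for 13 of 17 after reversal, also after each scaling, with Ciart, a repressor in the clock loop, at 23.9 ± 2.23 FPKM (SD, n = 4) in wild-type and 10.1 ± 7.91 FPKM in knockout livers and Usp2 at 17.6 ± 3.61 and 7.05 ± 4.57 FPKM. Red blood cell transcripts were lower for 9 of 9, also after each scaling, with Hbb-bs at 737 ± 718 and 307 ± 169 FPKM (exact permutation p = 0.257), and female-biased liver genes for 16 of 20 (17 after each scaling). The camera adjusted p of these lists were 9.5e-07, 7.5e-07 and 6.3e-08, and with an estimated correlation the adjusted p were 0.40 each. Cell cycle genes were higher for 25 of 27 (23 and 22 after the scalings), p53 targets for 21 of 23 (16 and 17) and vascular endothelial genes for 13 of 14 (12 and 11). These lists rose (camera adjusted p = 5.8e-04, 0.013 and 0.022, and adjusted p = 0.52, 0.47 and 0.59 with an estimated correlation). Each call was lost without knockout mouse 3, the cell cycle call also with a mean of at least 2 FPKM, the p53 call without wild-type mouse 3 or knockout mouse 2 and the vascular call without wild-type mouse 3 or 4 or knockout mouse 2. The cell cycle and p53 calls were also lost without wild-type mouse 1 and knockout mouse 3 together. Male-biased liver genes passed downward with 9 of 18 genes lower, 11 and 9 after the scalings (camera adjusted p = 0.0062, and adjusted p = 0.42 with an estimated correlation), a call lost after either scaling, with a mean of at least 2 FPKM and without knockout mouse 2 or 4. Kupffer cell, neutrophil, T and NK cell, B and plasma cell, sinusoidal endothelial and cholangiocyte markers did not pass (camera adjusted p = 0.33, 0.30, 0.32, 0.80, 0.17 and 0.30). The other 10 lists, the interferon response among them, had camera adjusted p from 0.066 to 0.87. Without knockout mouse 3 the mean log2 difference went from -0.30 to -0.18 for clock, -0.43 to -0.15 for female-biased, 0.34 to 0.18 for cell cycle, 0.31 to 0.19 for p53 and 0.32 to 0.20 for vascular genes, and without wild-type mouse 3 from -0.67 to -0.34 for red blood cell transcripts. Male-biased genes ranged from -0.39 (without knockout mouse 1) to -0.04 (without knockout mouse 2).

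Gene by gene, limma called 0 of 11032 genes after reversal (smallest adjusted p = 0.215), also with plain empirical Bayes, and 18 with library weights. At an unadjusted p under 0.05 there were 933 genes (767 higher and 166 lower, where chance gives 552), and the genotypes did not overlap for 399 genes higher and 109 lower, 4.605% against 2.86% by chance. Both chance values hold only where no gene is shifted. The 5 genes with the smallest p among those higher in the knockout were Acta2, Syne4, Foxs1, Socs3 and Tnip3 (limma adjusted p = 0.22 to 0.23). The 5 among those lower were Fbf1, Cyp4a10, Fkbp5, Cys1 and Por (limma adjusted p = 0.23 to 0.27). Fkbp5, a glucocorticoid-induced chaperone of the glucocorticoid receptor, stood at 28.1 ± 5.79 FPKM (SD, n = 4) in wild-type and 11.2 ± 3.43 FPKM in knockout livers.

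**Figure D3:**
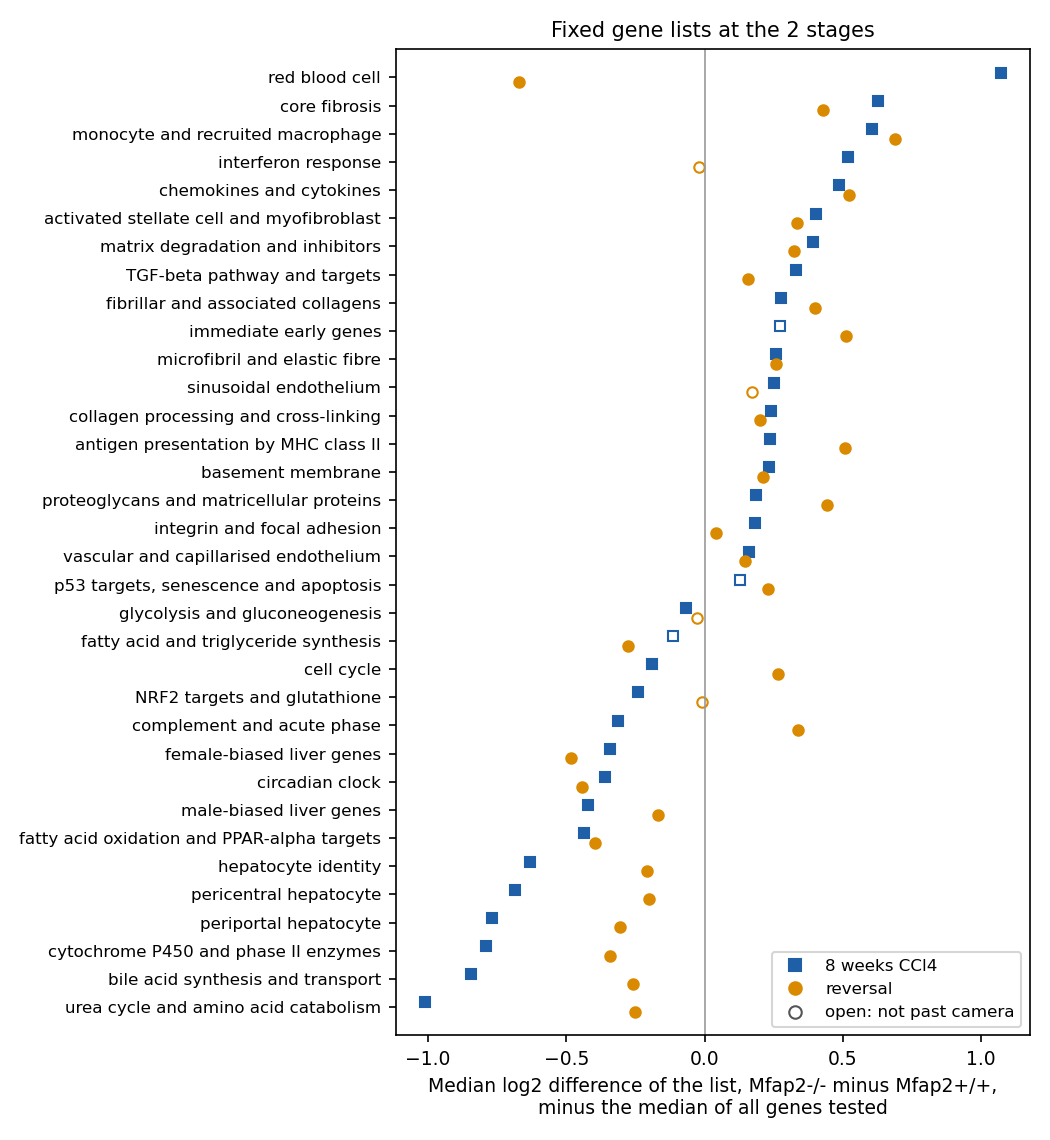
Median log2 difference between knockout and wild-type livers of each gene list past camera at either stage, minus the median of all genes tested at that stage; squares are 8 weeks of CCl4, circles reversal, and open symbols did not pass at that stage. The core fibrosis list lies at 0.63 and 0.43 and the urea cycle list at -1.01 and -0.25.

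The last comparison asked whether the effect of genotype differed between the stages. Of 10647 genes tested in both tables limma called 0 (smallest adjusted p = 0.166), with 294 at an unadjusted p under 0.05 where chance gives 532, and 10 with library weights. Across these genes the genotype differences of the stages correlated with a Pearson r of 0.47 and a Spearman rho of 0.446, although genes are not independent replicates. The sign was the same for 73.5%. As 82.6% of genes tested at 8 weeks and 70.7% after reversal were higher in the knockout, many share a sign through that shift alone. The 73.5% is therefore not read as agreement. Without knockout mouse 3 of the reversal group r was 0.293. With an estimated correlation 0 of 45 lists tested at both stages passed camera at both. With the preset correlation 27 did, 14 upward, 10 downward and 3 in opposite directions. Those 3 were red blood cell transcripts, higher at 8 weeks and lower after reversal, and complement and acute phase and cell cycle genes, lower relative to other genes at 8 weeks and higher after reversal. The 8-week calls of the last 2 were lost in 7 and 6 of 14 settings, median-ratio scaling among them. Without wild-type mice 1 and 2 both lists passed upward at 8 weeks as well. Tested directly, the core fibrosis list was not called as different between the stages (camera adjusted p = 0.88). The interferon list was, with a larger difference at 8 weeks (camera adjusted p = 2.0e-15), as were urea cycle genes (camera adjusted p = 7.5e-20). With an estimated correlation their adjusted p were 0.22 and 0.21.

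**Figure D4:**
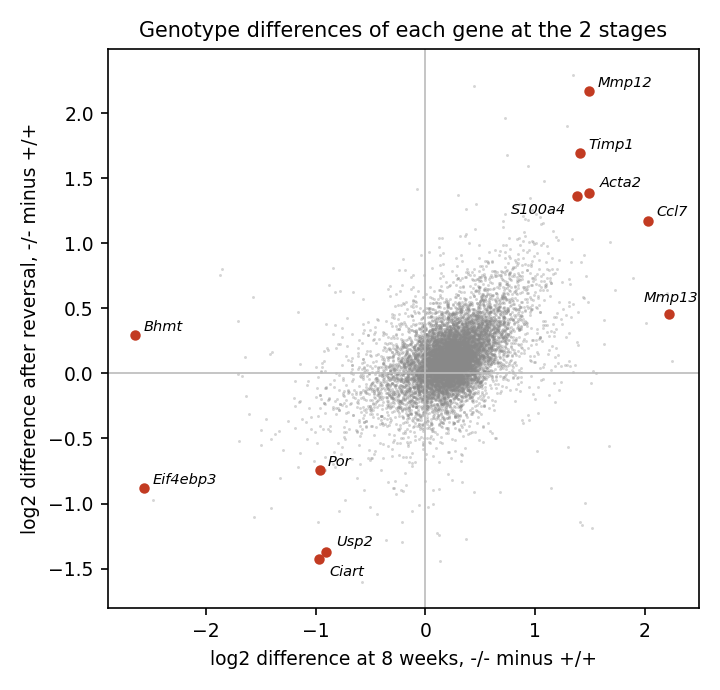
Log2 difference between knockout and wild-type livers of each of 10647 genes (grey dots) at 8 weeks (horizontal axis) and after reversal (vertical axis). The 11 genes marked were chosen after their values were seen; Mmp12, Timp1, Acta2, S100a4 and Ccl7 lie high at both stages, Eif4ebp3, Por, Usp2 and Ciart low at both, Mmp13 high mainly at 8 weeks and Bhmt low at 8 weeks alone, differences between stages that limma did not call.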

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

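Median-ratio scaling was planned, but the limits for reading it and the tests of the hepatocyte share and of exchanged labels in this part were chosen only after the result was seen.

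Matrix genes were higher in the knockout at both stages, with core fibrosis score differences of 0.82 and 0.67. Median-ratio scaling left 67.86% of the difference at 8 weeks and 85.65% after reversal, with no overlap between the genotypes, which argues against scaling by a few abundant transcripts as the whole cause. At 8 weeks a lower share of hepatocytes alone would raise pure markers of resident non-hepatocyte cells as much as the matrix genes. The matrix score exceeded the resident score by 0.4357 more in the knockout (exact permutation p = 0.0286). The gap between the highest wild-type mouse (-0.07) and the lowest knockout mouse (-0.03) was narrow. The resident score itself was 0.38 higher (exact p = 0.0286). Its lists were not checked for genes that hepatocytes also express (C6 is also in the male-biased liver list), and they did not rise evenly. Their mean log2 differences were 0.13 for Kupffer cell, 0.45 for sinusoidal endothelial and 0.52 for cholangiocyte markers. The excess therefore does not decide against a lower hepatocyte share. After reversal that excess was 0.4033 with overlap (exact p = 0.0857), so a lower hepatocyte share cannot be told apart from a change in matrix genes with 4 mice against 4. An effect of the Mfap2 genotype on fibrosis, or on the extent of the injury, may account for the pattern and stays open as untested, since genotype is the one label that separates the mice.

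Clock genes were lower and immediate early genes higher in the knockout after reversal. If the genotypes had been sampled at different times of day, evening and morning clock genes would move in opposite directions. The evening minus morning score differed by -0.4133 (exact permutation p = 0.114, pooled SD 0.25), with overlap, while evening genes differed by -0.48 and morning genes by -0.07. At 8 weeks, where clock genes were also lower as a list, evening genes differed by -0.35 and morning genes by 0.45, in opposite directions, and the score by -0.81 (exact permutation p = 0.143, pooled SD 0.58), again with overlap. With 3 morning genes tested after reversal and 4 at 8 weeks, and overlapping groups, a difference in time of day could not be excluded at either stage, and an effect of genotype was not tested separately.

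At 8 weeks the libraries parted more strongly when wild-type mouse 4 and knockout mouse 2 were exchanged, with 999 genes called by limma against 1 for the genotypes as labelled. Swapped labels of these mice may seem a possible explanation, but Mfap2 stood at 3.065 FPKM in the library labelled wild-type mouse 4 and was listed at 0 in the library labelled knockout mouse 2, which argues against it. The next largest split, with knockout mouse 4 in place of mouse 2, called 237 genes. Splits that call many more genes than the genotypes point to a structure of the samples, in which wild-type mice 1, 2 and 3 lie on one side, and what lies behind it stays open.

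Other splits of the libraries were counted for each number of calls. At 8 weeks 7 of 35 splits called at least as many genes as the genotypes (1, against a highest other of 999) and 4 of 35 at least as many lists (31, highest other 34), so chance cannot be excluded for either count. After reversal 5 of 35 splits called at least as many lists (30, highest other 33), and chance cannot be excluded there either. For genes after reversal (0 by limma with 933 at an unadjusted p under 0.05 and 18 with library weights, highest other 2) and for the stage difference (0 by limma with 294 at an unadjusted p under 0.05 and 10 with library weights, highest other 3) the count decides nothing, since all 35 splits and all 100 regroupings reach a count of 0.

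By camera with the preset correlation, 16 lists differed between the stages in their genotype difference, and 0 did with an estimated correlation (adjusted p = 0.19 to 0.997) or by fry (smallest adjusted p = 0.70). Relative to other genes the difference was lower after reversal for interferon response (adjusted p = 2.0e-15), red blood cell (5.4e-12), TGF-beta, fatty acid and triglyceride synthesis (0.0258 each) and cholesterol synthesis genes (0.0446). It was higher after reversal for urea cycle (7.5e-20), P450 and phase II (5.1e-15), complement and acute phase (1.2e-14), bile acid (9.5e-13), cell cycle (2.5e-09), hepatocyte identity (1.0e-06), periportal (1.4e-06), NRF2 (1.5e-05), pericentral (3.6e-05), immediate early (0.0179) and male-biased genes (0.0258). Nr1d1, a clock repressor, lay lower in every knockout mouse than in any wild-type mouse at 8 weeks (log2 difference -0.57) and higher in every one after reversal (0.58), a gap of 1.14 ± 0.31 (SE) that limma did not call over all genes (unadjusted p = 0.00137, adjusted p = 0.9999); 3 genes moved apart in this way, where chance gives 4.35.

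In 24 of 498 groups of 4 mice one library stood apart, its gap to the nearest other mouse exceeding 0.829 of the group's range, and chance does this in about 1 of 20 groups. At 8 weeks wild-type mouse 4 was high for Vcan (gap share 0.855), Plau (0.8301), Tgfbi (0.867) and Il1rn (0.9201) and low for Pfkfb1 (0.8337). Knockout mouse 3 was high for Col6a3 (0.8337), Col15a1 (0.8397), Tnc (0.858) and Plxnc1 (0.899) and low for Nr1d1 (0.9185). Wild-type mouse 3 was low for Cyp2c50 (0.917) and Cyp2c40 (0.928), wild-type mouse 1 high for Ciart (0.8505), wild-type mouse 2 high for H2-DMb1 (0.842) and knockout mouse 4 low for it (0.849). After reversal wild-type mouse 1 was high for Foxs1 (0.842) and Mup1 (0.8346) and low for Pck1 (0.941) and Cry2 (0.898). Knockout mouse 3 was high for Atf3 (0.8557) and Pdgfrb (0.829), knockout mouse 1 for Slco1a1 (0.8875) and Cyp7a1 (0.8804), and wild-type mouse 3 for Cyp7a1 (0.8563).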

How the results depend on the processing

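Fits without the libraries that stood apart, and the average effect of the stages, were added after the data were seen. The planned count-model alternatives were not run, because the tables hold no counts, and unknown depth limits what can be said of low genes. Of 4401 values of 247 gene results under the alternatives, 4156 kept direction and side of the threshold, 3 lost the call, 234 gained one and 8 reversed. As limma called 1 gene at 8 weeks and 0 after reversal, nearly all values kept are of genes that stayed uncalled. Mmp13, the gene called, was past the threshold in 15 of 18 alternatives. The cause of the changes below was not tested.

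Genes called at 8 weeks were 1 as fitted, 3 with a pseudocount of 0.1, 0 after median-ratio scaling, 2 with plain empirical Bayes, 1615 with library weights, 2 without wild-type mice 1 and 2, 46 in one fit over all 16 libraries and 189 (152 higher, 37 lower) at an unadjusted p under 0.05 with a 2-fold change. Leaving out one mouse gave 1 to 1465 (2 without wild-type mouse 1 or 2, 4 without wild-type mouse 3, 1465 without wild-type mouse 4, 32 without knockout mouse 2). After reversal limma called 0 in every alternative except library weights (18) and an unadjusted p with a 2-fold change (75). For the stage difference these were 10 and 81, and leaving out one mouse gave 0 to 1 (1 without wild-type mouse 3 of the 8-week group).

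Lists called were 31 and 30 as fitted, 2 and 0 with an estimated correlation and 0 and 1 by fry. Exact permutation tests of the per-mouse list scores, adjusted over the lists, called 0 at each stage (smallest adjusted p = 0.16 and 0.26). With camera as fitted, leaving out one mouse gave 27 to 33 and 21 to 34. Of the lists called as fitted, 17 (10 up, 7 down) and 18 (11 up, 7 down) kept call and direction. This holds for each of the 14 settings in which a list was tested. After reversal the microfibril list, counted among the 11 up, could not be tested with a mean of at least 2 FPKM.

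The core fibrosis score differences were 0.56 and 0.57 after median-ratio scaling and 0.62 and 0.54 after quantile normalization, with exact p = 0.0286 each. Leaving out one mouse gave 0.617 to 0.957 and 0.529 to 0.768. Without wild-type mice 1 and 2 the 8-week value was 0.676 (exact p = 0.133), and without wild-type mouse 1 and knockout mouse 3 the reversal value was 0.594 (exact p = 0.1). Mfap2 differences ranged from -1.42 to -1.06 and from -0.45 to -0.34 when one mouse was left out. By limma Mfap2 had an adjusted p of 0.056 at 8 weeks, from 7.7e-04 to 0.328 over 16 alternatives, 5 of them past the threshold.

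Same-numbered mice of the 2 genotypes did not deviate together (correlations -0.44 to 0.37 and -0.66 to 0.37, with 1 of 4 and 0 of 4 numbers matching best), so the numbers do not pair them. With the mouse number as a replicate block limma called 0 genes at 8 weeks and 155 for the average effect. The core score differences were 0.82 and 0.67 and the Mfap2 differences -1.30 and -0.40, with p = 0.125 in the exact test, the smallest that 16 sign flips allow.

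The average effect called 388 genes as fitted, 76 after median-ratio scaling, 55 after quantile normalization and 39 without the 4 libraries that stood apart, and 53 to 1409 with one mouse left out. The correlation between stages was 0.454 to 0.494 in the other settings and 0.293 to 0.502 with one mouse left out.

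Reversed log2 differences at 8 weeks were those of Plk1 (0.00158 without wild-type mouse 2, 0.0637 without mice 1 and 2) and, without wild-type mice 1 and 2, Ccnb2 (0.11), Birc5 (0.29), C6 (0.19), Serpina1e (0.0721) and Mmp2 (-0.0437). Leaving out one mouse gave -0.37 to 0.00158 for Plk1. After reversal Mup1 was at 0.10 without wild-type mouse 1 and knockout mouse 3.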

Other observations

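The average of the genotype effects of both stages, the genes named for it and the regroupings with one mouse left out were chosen after the values were seen. Averaged over the stages, the log2 difference was 1.83 ± 0.35 (SE) for Mmp12, 1.603 ± 0.26 for Ccl7, 1.38 ± 0.23 for S100a4, 1.35 ± 0.27 for Tagln and 1.28 ± 0.21 for Actg1, a cytoplasmic actin, each without overlap between the genotypes at both stages (limma adjusted p = 0.0187, 0.0081, 0.0089, 0.0191 and 0.0081). The acute phase gene Saa1 stood at 1.82 ± 0.45 and Timp1 at 1.55 ± 0.31 (limma adjusted p = 0.0373 and 0.0191), with overlap at 8 weeks for Saa1 and after reversal for Timp1. Among genes lower in the knockout, Por stood at -0.85 ± 0.14, without overlap at both stages, Eif4ebp3 at -1.72 ± 0.25, and Fkbp5 and Zbtb16, which glucocorticoids induce, at -0.82 ± 0.17 and -0.85 ± 0.18 (limma adjusted p = 0.0081, 0.0059, 0.0191 and 0.0197). Bhmt averaged -1.17 but differed by -2.64 at 8 weeks and 0.29 after reversal.

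Over all 10647 genes limma called 388 for the average effect (356 higher, 32 lower), and 2252 at an unadjusted p under 0.05. After median-ratio scaling the count was 76 (45 higher, 31 lower; 67 shared with the 388) and after quantile normalization 55 (33 higher, 22 lower; 48 shared). All 388 kept their direction in these settings. The count was 68, 101, 177 and 1409 without wild-type mouse 1, 2, 3 or 4 of the 8-week group, 123 and 66 without knockout mouse 1 or 3 of it, 584, 53 and 87 without wild-type mouse 1, 2 or 4 of the reversal group and 111 without knockout mouse 3 of it. For 70 genes higher and 5 lower the genotypes did not overlap at either stage, where chance gives 4.35 if no gene is shifted. As deposited the median gene lay 0.23 and 0.10 higher in the knockout at the 2 stages, so the excess is not read as a count of changed genes. Of 100 regroupings 2 gave as many calls, the real one included, with a highest other of 1434 and a next of 3. As many calls were thus rare, but a regrouping that ignores genotype gave more than the real one. This points to a structure of the samples, so chance is not excluded for this count.

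The genotype effects of the stages come from different mice. Their correlation across genes, 0.47, was the highest of 100 regroupings (1 as large, the real one, with a highest other of 0.418). With all 16 mice, chance regrouping thus seldom gave a correlation of this size. Without knockout mouse 3 of the reversal group the value fell to 0.293, below 7 of those regroupings. Among 100 regroupings of the remaining mice 3 were as large, the real one included (highest other 0.381). The size of the correlation thus leans on this mouse, and chance is not excluded without it. With any other mouse left out, 1 or 2 of 100 were as large. The mean of the core fibrosis score differences of both stages was 0.74 (exact permutation p = 4.1e-04, the smallest that 4900 assignments can give). As the knockout was higher without overlap at both stages, this p could take no other value. It restates the results of the single stages and is no further test.

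One hypothesis was that differences shared by the stages may come from flanking DNA carried with the Mfap2 allele. Within 10 Mb of Mfap2, 8 of 177 genes (4.52%) had an unadjusted limma p under 0.05 in the same direction at both stages, against 332 of 10470 elsewhere (3.17%, one-sided Fisher exact p = 0.2054). The share near Mfap2 was not shown to be higher, and with 8 genes it cannot be told apart from that elsewhere. In all, 340 genes met this criterion, 316 higher and 24 lower in the knockout. Chance gives 13.3 where no gene is shifted, but as deposited the median gene lay 0.23 higher in the knockout at 8 weeks and 0.10 after reversal, so the excess is not read as a count of changed genes.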
